A study of Bos taurus with 34 samples.

How the data were processed

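The series measured polyadenylated RNA in single bovine preimplantation embryos that carried a knockout of CSF2RA, or were controls. Sample titles give the knockouts as CSF2KO, which names the ligand, where the series title and design speak of CSF2RA, which was used here. Per the labels there were 34 embryos. Of these, 26 were blastocysts, 9 knockout and 17 control, and 8 were morulae, 4 knockout and 4 control. Knockout blastocysts were 7 females and 2 males, and control blastocysts 8 females and 9 males. Knockout morulae were 3 females and 1 male, and control morulae 1 female and 3 males. Each embryo was taken as 1 replicate, and its genotype, stage and sex came from the labels. For control blastocyst 72 the title gives male and the column name of the deposited table gives female; the title was used, and the other reading was tried. For every sample the treatment protocol in the labels names added recombinant Wnt5A and the growth protocol names development in vitro, where the series title speaks of expression in utero. The treatment characteristic is another field, which holds the sex. Groups were taken from titles and characteristics, and which protocol holds was not settled.

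Per the labels, the authors extracted RNA with a column kit, made stranded libraries after poly(A) selection, assessed reads with FastQC, counted reads per gene with featureCounts and tested genes with edgeR, on the ARS-UCD1.2 assembly. The labels give no versions of these tools. The deposited values were RPKM per gene and embryo, in 1 table for blastocysts with 18442 genes and 1 for morulae with 14878 genes. The morula table does not name its unit, and RPKM was inferred from the values. In both tables the values equal whole reads divided by the genomic span of the gene, introns included, and by an effective library size per embryo. Reads counted back in this way were whole for 100% of the genes of every embryo, within a tolerance of 0.01 reads. RPKM over the genomic span understates genes with long introns relative to compact genes, so levels are compared between embryos and not between genes. The tables were normalized separately, so levels set side by side across stages also hold any difference in scaling. The deposited tables also hold the authors' log2 fold change between genotypes with a p-value and an FDR per gene, from a model with sex as a block, which are reported as such.

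The main test was limma-trend in limma 3.58.1 (R 4.3.3) on log2(RPKM + 1), with robust empirical Bayes moderation, two-sided, and Benjamini-Hochberg adjustment at 0.05. A count test was not used for the main results because the tables hold normalized values. Genes needed an RPKM of at least 1 in as many embryos as the smaller genotype group, which is 9 blastocysts, 4 morulae, 7 female blastocysts or 2 male blastocysts. Genotype was compared with sex as a term in blastocysts and in morulae, and then within female and within male blastocysts. The interaction of sex and genotype was tested in all blastocysts, and males were compared with females with genotype as a term. Log2 changes are knockout minus control, or male minus female, with the SE of the fit. Single genes that failed the filter were fitted in a run without it.

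Before the data were examined, 31 gene lists were fixed from textbook knowledge, for embryonic lineages, signalling, stress and cell death, metabolism, sex chromosomes and other cell types. Lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. Fry was run as an alternative that asks another question, whether a list changed at all, without reference to other genes. The p-values of 24 lists per stage were adjusted together. A mean log2(RPKM + 1) per embryo was also computed for each list that had a tested gene and compared between genotypes, by permutation within sex with 1e+05 resamples in blastocysts and by exact permutation in morulae. The exact permutation exchanged all 8 morulae without regard to sex. With 4 embryos against 4 the smallest two-sided exact p is 0.0286. Library measures were compared between genotypes and between sexes by permutation over all blastocysts and by exact permutation in morulae, adjusted over 20 tests. Those of blastocysts by genotype were also permuted within sex, after seeing the data.

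Named genes followed a rule fixed before the data were examined. CSF2RA and CSF2RB were always named. In each direction the 10 genes with a symbol, a mean of at least 1 RPKM in 1 of the genotypes and the largest change among those passing were named, or 5 for the sex comparison, and empty places went to the smallest unadjusted p. Genes that pass within a list, and for each list described 2 to 4 members with the smallest p, were added. Genes called in the deposited tables are described apart from this rule. Some genes that the rule names are not reported here.

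Totals of recovered reads ran from 44879 to 17598170 in blastocysts and from 43679 to 1526852 in morulae. One read was 0.0644 CPM in the deepest library, control blastocyst 37, and 25.5 CPM in knockout morula 21. The limit that a count of 0 allows, 3 reads, was 0.193 CPM and 76.4 CPM in these libraries. Shares of reads in single embryos carry 95% Wilson intervals. Reads were not molecule-counted, so intervals and limits cover counting error only. A library was held in doubt with fewer than 5000 genes detected or fewer than 50000 reads, limits set after the libraries were seen.

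Alternatives fixed beforehand changed the pseudocount to 0.1 or 0.5, dropped the filter or set it at a mean of 5 RPKM, rescaled embryos by median ratios or quantiles, dropped robust moderation, weighted embryos by quality, dropped the other factor, split the sexes, took the authors' table, and left out each embryo in turn. Alternatives chosen after seeing the data were voom on the recovered reads with at least 5 reads, CPM with a minimum of 10, leaving out the libraries in doubt, keeping only blastocysts with over 1.5% of reads on the 2 bta-mir-2887-1 genes, the other sex of embryo 72, quality weights without the libraries in doubt, and the list tests by sex, within females and of the interaction without control blastocyst 12 or without the libraries in doubt. The bta-mir-2887-1 limit left out control blastocysts 12, 35, 36, 37, 51 and 52. It left out no knockout, as the lowest share among knockout blastocysts was 1.849%, so it changed the control group only. The tests were tried on simulated counts with the depths and group sizes of these embryos. Permutations, library measures and figures used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No deposited column was left out.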

Results

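RNA was sequenced from 34 single bovine embryos, so that each value below comes from 1 embryo, whose genotype, stage and sex come from the labels. CSF2RA encodes the ligand-binding subunit of the receptor for CSF2, a cytokine of the reproductive tract. The blastocysts were 9 knockouts and 17 controls, and the morulae were 4 knockouts and 4 controls. Blastocyst libraries held 44879 reads (knockout 57) to 17598170 reads (control 37) in genes, and morula libraries 43679 reads (knockout 49) to 1526852 reads (control 39). The median blastocyst library held 254800 reads in knockouts and 878069 in controls (permutation p = 0.0431, adjusted p = 0.163; permutation within sex p = 0.11). The median morula library held 87890 reads in knockouts and 314121.5 in controls (exact permutation p = 0.0571, adjusted p = 0.163). Knockout morulae had a median of 6408 detected genes and control morulae of 10710 (exact permutation p = 0.0571, adjusted p = 0.163).

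**Figure D1:**
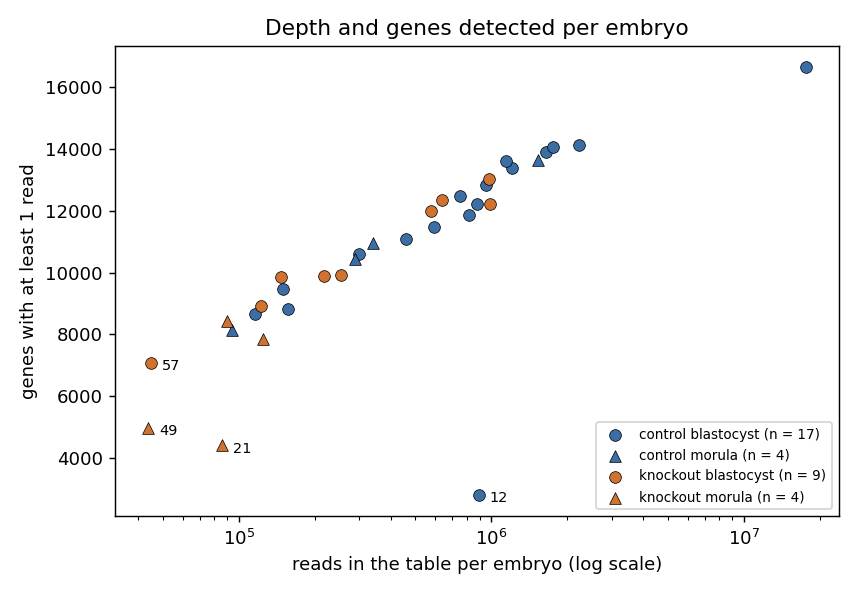
Reads in the table per embryo (x axis, log scale) against genes with at least 1 read (y axis), with circles for blastocysts, triangles for morulae, blue for controls and orange for knockouts. Control blastocyst 12 had 2791 genes at 893152 reads, and knockout morulae 21 and 49 had 4392 and 4956 genes.

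A few transcripts took large shares of single libraries. Mitochondrially encoded genes took 35.8% of the reads of control blastocyst 12 (95% Wilson interval 35.7% to 35.9%), where the median of control blastocysts was 4.62%. In knockout morula 21, NPAT, a histone gene transcription regulator, took 36.2% of reads (interval 35.9% to 36.6%) and GSC2 took 28.9% (interval 28.6% to 29.2%). In knockout morula 49, GSC2 took 18.7% (interval 18.3% to 19.0%). Among control morulae, ANKRD9 took 13.85% of reads in control 73 (interval 13.63% to 14.07%). The 2 genes with the symbol bta-mir-2887-1, a microRNA, together ranged from 0.00675% of reads in control morula 54 to 8.63% in knockout blastocyst 75. Control blastocyst 12, knockout blastocyst 57 and knockout morulae 21 and 49 are the 4 libraries in doubt.

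The edited gene and its partner were barely sequenced. CSF2RA (ENSBTAG00000045948, chromosome 3, 119425809 to 119430912) had 4 reads over all blastocysts, of which 2 fell in knockout 57, 1 in control 35 and 1 in control 37. That is 6.49 RPKM in knockout 57, 1.37 RPKM in control 35 and 0.0126 RPKM in control 37, and every other blastocyst was listed at 0. CSF2RB (ENSBTAG00000009064, chromosome 5, 75349088 to 75370432), the signal-transducing subunit, had 3 reads in knockouts and 3 in controls. Neither gene passed the RPKM filter, and both are absent from the morula table. The fitted change was 0.25 ± 0.26 (SE) for CSF2RA (permutation within sex p = 0.904) and 0.14 ± 0.11 for CSF2RB (permutation p = 0.201), each with 9 knockouts and 17 controls. Without knockout 57 these were −0.05 and 0.0027, and with a pseudocount of 0.1 they were 0.463 and 0.4139. A loss or a gain of either transcript was not detectable at this depth, and whether the locus on chromosome 3 is the edited one could not be settled from the tables.

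Downstream kinases and transcription factors of the receptor had low counts as well. JAK2 had 146 reads in blastocysts (permutation p = 0.074), STAT5A had 42 (permutation p = 0.915) and STAT5B had 179 (permutation p = 0.0832, adjusted p = 0.222). In morulae STAT5B was listed at 0 in all 4 knockouts, and it had 19 reads over the 4 controls, a mean of 10.4 CPM where a count of 0 allows up to 9.10 CPM (exact permutation p = 0.0286, adjusted p = 0.222). That mean weighs each control alike, while the limit pools reads over the knockouts. With the 2 this close, the 0 shows no clear lower level. Of the list for the CSF2 receptor and its signalling, 10 genes were tested in blastocysts and 8 in morulae, and the list was not called (camera adjusted p = 0.82 and 0.861). Targets of STAT5 gave an adjusted p of 0.82 in blastocysts and 0.908 in morulae. Among them CCND2, a cyclin of the G1 phase, averaged 9.35 ± 1.77 RPKM (SD) in 9 knockouts and 7.92 ± 4.82 RPKM in 17 controls.

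Knockout and control blastocysts were compared to find transcripts that the receptor affects in embryos of the same stage. The list with the smallest p was cholesterol biosynthesis, where 15 of 17 tested genes were lower in knockouts; it was called with a preset correlation and not with an estimated one (adjusted p = 0.542). FDPS, which makes farnesyl diphosphate, averaged 3.07 ± 1.23 RPKM (SD, n = 9) in knockouts and 12.1 ± 18.7 RPKM (n = 17) in controls, and all 9 knockouts lay below the control median. INSIG1, a sterol-responsive regulator of that pathway, averaged 0.602 ± 0.544 RPKM against 3.50 ± 3.40 RPKM. MSMO1, a sterol oxidase, had a log2 change of −0.54. The median log2 change of the list was −0.42, when that of all tested genes was 0.08. Without control 12 these medians were −0.48 and −0.07.

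As a set these genes fell relative to other genes with the preset correlation (camera adjusted p = 9.7e-08). The adjusted p was 0.542 with an estimated correlation, so the call did not hold there. Above the bta-mir-2887-1 limit, which left out controls only, the median of the list was −0.72. No member passed over all genes, and 1, FDPS (log2 change −1.29 ± 0.35 SE), passed when adjusted over the list alone (0.0192). The mean of the list was 1.63 ± 0.32 in knockouts and 2.11 ± 0.63 in controls on the log2 scale, lower than the control median in 8 of 9 knockouts (permutation within sex p = 0.0758, adjusted p = 0.981 over 31 lists).

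The 13 mitochondrially encoded genes formed the other list that passed, with 12 lower in knockouts and a median of −0.30 (camera adjusted p = 9.93e-06, and adjusted p = 0.542 with an estimated correlation). ATP8, a subunit of ATP synthase, had a log2 change of −0.71, and the cytochrome oxidase genes COX2 and COX3 had −0.48 and −0.47. None passed over all genes or adjusted over the list alone. This call rested on control blastocyst 12, the library with the high mitochondrial share, and without it the median was −0.15 and the adjusted p 0.368. The median was −0.48 without knockout 75 and −0.20 without knockout 58.

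Lineage genes were not called as lists. Among 16 epiblast and pluripotency genes (adjusted p = 0.758), TDGF1, a co-receptor of NODAL, averaged 1.14 ± 1.76 RPKM (n = 9) against 9.52 ± 25.0 RPKM (n = 17). NANOG had a log2 change of −0.81 and KLF4 one of 0.76, and no member passed adjusted over the list alone. Of 27 trophectoderm genes 15 were lower (median −0.04, adjusted p = 0.292), with CDX2 at 17.1 ± 8.76 RPKM against 18.1 ± 7.35 RPKM. Without control blastocyst 12 the trophectoderm list was called lower with the preset correlation (median −0.37, adjusted p = 0.00505). With an estimated correlation, tried over all blastocysts, its adjusted p was 0.96. The epiblast and hypoblast lists had medians of 0.05 and 0.07, above 0, where camera placed them below other genes. The 12 hypoblast genes gave an adjusted p of 0.758, the 23 cell junction genes 0.833 and the 15 WNT genes 0.758.

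Stress and energy lists were also short of the threshold in blastocysts. Among 20 genes of the p53 response 15 were higher (median 0.29, adjusted p = 0.186), and PHLDA3, a p53 target, averaged 135 ± 80.7 RPKM (n = 9) against 81.0 ± 61.1 RPKM (n = 17). That count holds the shift of all tested genes too, whose median was 0.08, or −0.07 without control 12. Glycolysis gave an adjusted p of 0.0814, or 0.0426 and lower without the libraries in doubt, and ENO1, or enolase, averaged 46.3 ± 15.9 RPKM against 68.6 ± 23.8 RPKM. The 69 nuclear genes of oxidative phosphorylation gave 0.82, though they were called higher above the bta-mir-2887-1 limit (2.13e-11) and without control 52 (0.0259). Without sex in the model the p53 response was called higher (0.0197). These calls used the preset correlation, and with an estimated one, tried over all blastocysts, no list was called. Over all blastocysts, cell cycle genes gave 0.279, interferon response genes 0.346, antioxidant genes 0.186 and chromatin genes 0.758. Markers of cumulus cells, oviduct epithelium, leukocytes, erythrocytes and fibroblasts, with 1 to 4 genes past the filter each, gave permutation p from 0.115 to 0.893 (adjusted p = 0.981).

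**Figure D2:**
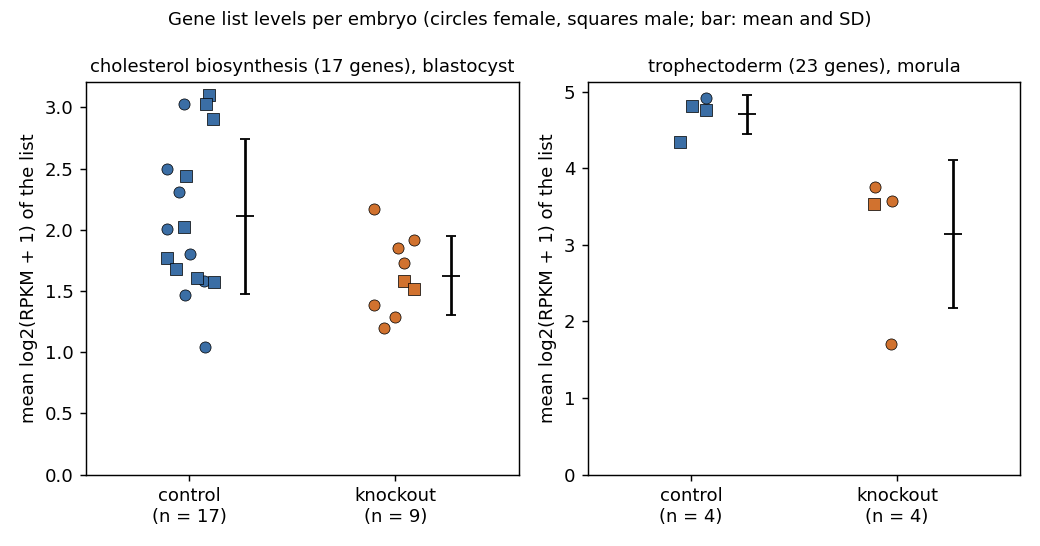
Mean log2(RPKM + 1) per embryo (y axis) of 17 cholesterol biosynthesis genes in blastocysts and of 23 trophectoderm genes in morulae, by genotype (x axis), with circles for females, squares for males and bars for mean and SD. The cholesterol mean was below the control median in 8 of 9 knockouts, and the trophectoderm mean was below every control in all 4 knockout morulae.

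Gene by gene, limma-trend called 0 of 6283 genes between knockout and control blastocysts, and the smallest adjusted p was 0.994. At an unadjusted p under 0.05 there were 173 genes, 113 higher and 60 lower, where 314 would be there by chance. Voom on the recovered reads also called 0, with 238 higher and 27 lower at that unadjusted p. The balance turned to 125 higher and 313 lower with quality weights, 147 and 335 above the bta-mir-2887-1 limit, and 109 and 124 with quantile scaling. It was 95 and 132 without the libraries in doubt, control 12 and knockout 57. Of the genes named for the smallest p, none of which passed, FICD, an enzyme that modifies the chaperone BiP, averaged 3.51 ± 1.38 RPKM in knockouts and 1.63 ± 1.15 RPKM in controls. All 9 knockouts lay above the control median for FICD. GJA4, a gap junction protein, averaged 3.27 ± 3.90 RPKM against 0.688 ± 1.32 RPKM. SUN2, a nuclear envelope protein, averaged 5.84 ± 2.31 RPKM against 3.42 ± 1.48 RPKM. The other higher genes were TMEM200B, SLC2A4RG, SPATA2, SEPTIN5, PDXP, ATP1B2 and CAMK2N2, with log2 changes from 0.79 (ATP1B2) to 1.17 (SLC2A4RG). The lower genes besides FDPS, INSIG1 and TDGF1 included TSPAN17, KCNK7, HBQ1, PAIP1, POLR2K and HMGN5, from −0.42 (PAIP1) to −1.48 (HBQ1).

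The authors' deposited table calls 15 genes between knockout and control blastocysts at an FDR of 0.05, 10 higher and 5 lower in knockouts, in a test that differs from the one above in scale and filter. The smallest FDR belongs to RAB33A, a small GTPase on chromosome X, with a deposited log2 change of 4.87 and an FDR of 1.82e-05. Of its 1428 knockout reads, 1380 came from knockout 75. THBS1, a matrix glycoprotein, had 49 knockout reads, 46 of them in knockout 31. AREG, a ligand of the EGF receptor, had 18 knockout reads in 4 embryos and 3 control reads. PPP1R8 had 2129 of its 2207 knockout reads in knockout 58, and NAGPA had 645 of 795 in knockout 17. Among the lower genes, VAMP5 had 10735 of 10758 control reads in control 61. TREM2 had 1256 of 1257 in control 12, and UNCX (655 reads), KCTD14 (961 reads) and SLC22A17 (622 reads) were also highest in control 12. The remaining genes, DNAH14, LAMP5, ATP13A4, ADIRF and UPK1B, had 6 to 11 knockout reads each. RAB33A was detected in 8 of 9 knockouts and 14 of 17 controls.

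**Figure D3:**
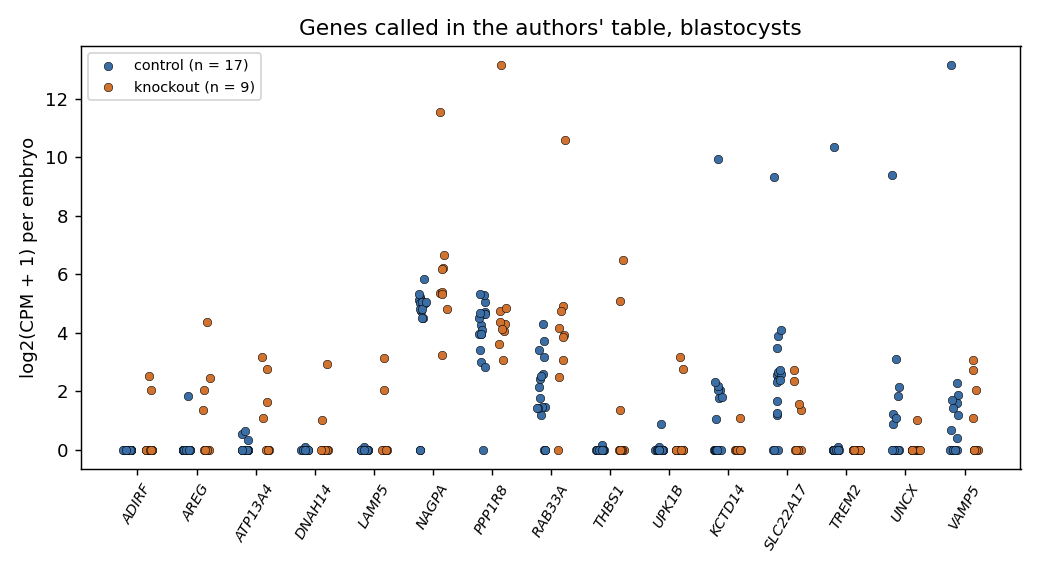
Level of each of the 15 genes called in the authors' blastocyst table, as log2(CPM + 1) per embryo (y axis), by gene (x axis), with 1 point per embryo, knockouts apart from controls by colour. For 14 of 15 genes, 1 embryo held over 50% of the CPM of the higher genotype, as for VAMP5 in control 61.

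Knockout and control morulae were compared to ask the same before the blastocyst forms. The list that was called was trophectoderm, with 22 of 23 tested genes lower in knockouts; it was called with a preset correlation and not with an estimated one (adjusted p = 0.929). PAG2, a trophoblast glycoprotein, averaged 0.850 ± 0.982 RPKM (SD, n = 4) in knockouts and 20.6 ± 16.9 RPKM (n = 4) in controls. PTGS2, the inducible prostaglandin synthase, averaged 8.45 ± 14.1 RPKM against 66.3 ± 16.9 RPKM. DLX3 and ELF3, transcription factors of trophoblast and epithelium, averaged 0.397 ± 0.793 RPKM against 3.87 ± 3.03 RPKM, and 1.27 ± 2.53 RPKM against 7.85 ± 2.98 RPKM. For each of these 4 genes every knockout lay below the control median. CDX2, a regulator of trophectoderm fate, averaged 6.68 ± 6.59 RPKM against 12.4 ± 7.11 RPKM.

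As a set the trophectoderm genes fell relative to other genes with the preset correlation (median −0.99, when all tested genes had −0.34; camera adjusted p = 0.000717). With an estimated correlation the adjusted p was 0.929, and the call did not hold. The median was −2.13 without knockout morula 1 and −1.57 with a pseudocount of 0.1. No member passed over all genes, and 4 passed when adjusted over the list alone. These were PAG2 (−3.62 ± 0.84 SE), DLX3 (−2.21) and PTGS2 (−4.22 ± 1.12), each at 0.0306, and ELF3 (−2.69) at 0.0403. The mean of the list was 3.14 ± 0.97 in knockouts and 4.71 ± 0.25 in controls, with 4 of 4 knockouts lower (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.123 over 30 lists). This permutation ignored sex, where 3 of 4 knockouts were females and 3 of 4 controls males. The same exact p and adjusted p belonged to the lists for hypoblast, cell junctions, the p53 response, glycolysis, ER stress and cumulus cell markers. Knockout morulae 21 and 49 were also the morula libraries with the fewest genes.

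Other groups of the morulae were lower in the list means without passing camera. The list mean was lower in knockouts for each of the 30 lists compared, and all tested genes had a median of −0.34. Counts of lower genes below hold that shift too. Cell junction genes had 18 of 20 lower (adjusted p = 0.204), with CLDN4, a tight junction claudin, at 62.8 ± 48.2 RPKM (n = 4) against 268 ± 139 RPKM (n = 4). The ER stress list had 13 of 16 lower (adjusted p = 0.266). The chaperones HSPA5, at 34.9 ± 9.97 RPKM against 145 ± 43.6 RPKM, and HSP90B1, at 7.37 ± 3.94 RPKM against 30.1 ± 8.25 RPKM, were the 2 members that passed when adjusted over the list alone (0.043 each). Glycolysis had 13 of 15 lower (adjusted p = 0.204), with ENO1 at 15.2 ± 8.86 RPKM against 66.97 ± 16.7 RPKM. In the p53 response 14 of 18 were lower (adjusted p = 0.527), 2 members passed adjusted over the list alone, GADD45G and TRIAP1, and PHLDA3 went the other way with 339 ± 193 RPKM against 111.5 ± 93.7 RPKM. Without the libraries in doubt the cell junction (adjusted p = 0.0332) and glycolysis lists (0.0254) were called lower and nuclear oxidative phosphorylation genes higher (0.0113). That run used the preset correlation, and with an estimated one, tried over all morulae, no list was called. Over all morulae, hypoblast genes gave an adjusted p of 0.908, epiblast genes 0.733, cholesterol genes 0.988, mitochondrially encoded genes 0.606, nuclear oxidative phosphorylation genes 0.965, cell cycle genes 0.733, interferon response genes 0.667, antioxidant genes 0.861, chromatin genes 0.527 and WNT genes 0.667.

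Gene by gene, limma-trend called 0 of 5021 genes between knockout and control morulae, and the smallest adjusted p was 0.0694. At an unadjusted p under 0.05 there were 345 genes, 45 higher and 300 lower, where 251 would be there by chance. These were 49 higher and 252 lower with median ratio scaling, and 171 and 191 with quantile scaling, which makes the distributions of all embryos equal by construction. Voom on the recovered reads called 1 gene, GCA, a calcium-binding protein, at −4.26 (adjusted p = 0.0152), with 72 genes higher and 269 lower at the unadjusted p. GCA averaged 0.119 ± 0.239 RPKM in knockouts and 6.75 ± 4.38 RPKM in controls (n = 4 each).

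Of the genes named for the smallest p, none of which passed limma-trend, H3C7 (a histone H3 gene), CHST14 and MYL7 were listed at 0 in all 4 knockouts. They averaged 13.2 ± 8.07, 7.71 ± 5.59 and 9.38 ± 10.3 RPKM in controls. GADD45G, a stress-induced growth inhibitor, was also listed at 0 and averaged 6.04 ± 1.51 RPKM in controls. The others, at 0 as well, were TMEM150B, TRIAP1, CXCL5, TMEM251 and TMUB2, each with an adjusted p of 0.0694. A count of 0 allows up to 9.10 CPM over the knockout morulae, above the 5.40 CPM of controls for H3C7, so that 0 shows no lower level. The control means of the others lay above it, from 10.8 CPM (GADD45G) to 27.4 CPM (TMUB2). That limit pools reads over the knockouts, while the control mean weighs each control alike, the shallow ones included. A mean close to the limit, as for GADD45G, therefore shows no clear lower level. On the higher side IL18BP, a decoy receptor of IL18, averaged 19.1 ± 15.01 RPKM against 4.28 ± 3.34 RPKM. TRIB2 averaged 3.17 ± 1.11 RPKM against 0.624 ± 0.254 RPKM, and CEP131, a centriolar satellite protein, 2.68 ± 1.08 RPKM against 0.502 ± 0.581 RPKM. The others were PRDM12, ZMIZ2, PATZ1, SHISA8, PHLDA3, KBTBD8 and SMG9, with log2 changes from 1.35 (SMG9) to 3.48 (PATZ1).

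The authors' deposited table calls 27 genes between knockout and control morulae, 17 higher and 10 lower in knockouts. All 10 lower genes have symbols. APOA1, the main protein of high-density lipoprotein, had 10 knockout reads and 438 control reads (deposited log2 change −5.03, FDR 7.24e-06). PAG2 had 4 and 268 reads, PLAU, the urokinase protease, had 8 and 511, GCA had 1 and 189, and PTGS2 had 14 and 1480. ARPC1B, a subunit of the actin-nucleating ARP2/3 complex, had 9 and 410 reads. PTPRJ, a receptor tyrosine phosphatase, had 0 and 214 reads, PLEKHO2 had 0 and 110, SLC13A4 had 0 and 85, and PAGE4 had 0 and 40. A count of 0 allows up to 9.10 CPM over the 4 knockout morulae, where the controls averaged 71.7 CPM for PTPRJ and 62.5 CPM for PLEKHO2. For 8 of the 10 genes every control was above every knockout, with APOA1 and PAGE4 the exceptions. Control 73, the shallowest control, held 78.52% of the control CPM for PAGE4, 71.25% for APOA1, 57.21% for SLC13A4 and 53.52% for PAG2. For the other lower genes no control held over 50%. Of the 17 higher genes 15 have no symbol, and UPK3BL1 and PTMA have one. For 16 of these 17 genes 1 knockout held over 50% of the knockout CPM, and for 15 of them that was knockout 1, with up to 38 reads a gene. PTMA had 14 of its 15 knockout reads in knockout 1, and UPK3BL1 had 8 of its 12 in knockout 21.

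**Figure D4:**
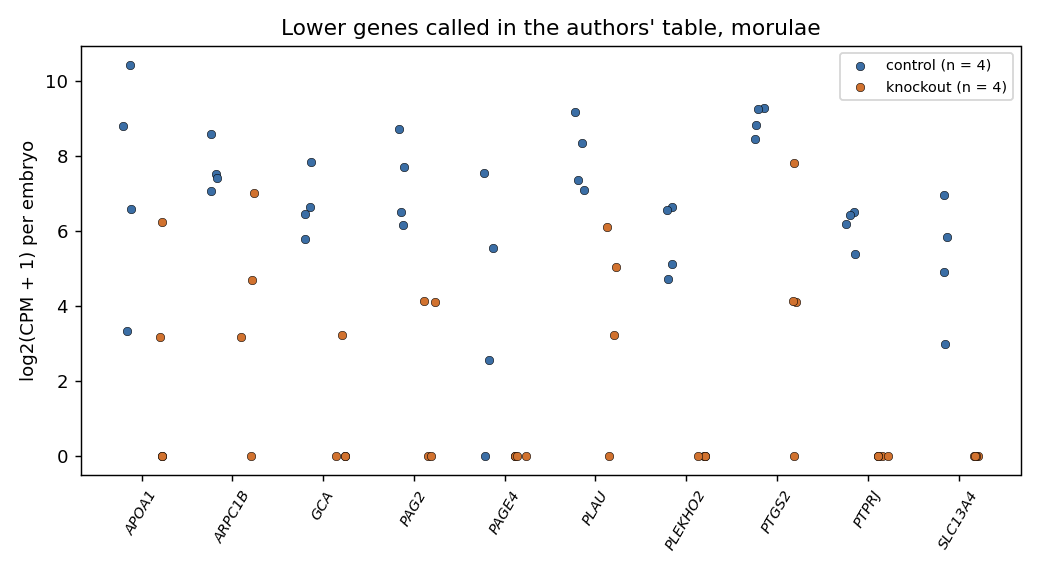
Level of each of the 10 genes lower in knockouts in the authors' morula table, as log2(CPM + 1) per embryo (y axis), by gene (x axis), with 1 point per embryo, knockouts apart from controls by colour. PTPRJ, PLEKHO2, SLC13A4 and PAGE4 had 0 reads in every knockout, and PTGS2 had 14 reads over the 4 knockouts and 1480 over the 4 controls.

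Genotype was then compared within each sex of blastocyst, since 2 of 9 knockouts and 9 of 17 controls were males. Knockout 57 was kept among the females by its label, though its X-linked level (−0.45) lay in the male range. No run took knockout 57 as a male. Among the genes named in females (7 knockouts, 8 controls), TDGF1 averaged 0.728 ± 1.01 RPKM against 17.2 ± 35.9 RPKM. FOXH1, a transcription factor of NODAL signalling, averaged 1.05 ± 1.80 RPKM against 7.06 ± 5.37 RPKM, and FDPS 2.87 ± 1.30 RPKM against 16.4 ± 27.2 RPKM. All 7 female knockouts lay below the control median for each of these 3 genes. HES6, a transcription factor of the HES family, averaged 25.4 ± 30.4 RPKM against 2.35 ± 2.44 RPKM. None of the named genes passed, and limma-trend called 0 of 5735 genes (smallest adjusted p = 0.243), with 71 higher and 37 lower at an unadjusted p under 0.05, where voom called 0 with 91 and 14. The balance turned to 159 higher and 389 lower with quality weights, 108 and 277 above the bta-mir-2887-1 limit, and 90 and 144 without the libraries in doubt. Mitochondrially encoded genes (median −0.56, camera adjusted p = 1.28e-09) and cholesterol genes (median −0.20, adjusted p = 0.000203) were lower as lists. With an estimated correlation their adjusted p were 0.313 and 0.561. Without control 12, the library with the high mitochondrial share, the medians were −0.31 and −0.40, each with an adjusted p of 0.00478, and 0.643 with an estimated correlation.

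In males (2 knockouts, 9 controls) 2 genes passed. HSD11B1L, a short-chain dehydrogenase, fell to 0.675 ± 0.0254 RPKM (SD, n = 2) from 4.27 ± 0.882 RPKM (n = 9), with a log2 change of −1.64 ± 0.22 (limma adjusted p = 0.0425). A gene without a symbol, ENSBTAG00000047911, averaged 2.77 ± 0.683 RPKM in the 2 knockout males, from 4 reads in all. It was listed at 0 in all 9 control males (limma adjusted p = 0.0185). At an unadjusted p under 0.05 there were 361 of 7604 genes, where 380 would be there by chance. With 2 knockout males, neither call held with voom or above the bta-mir-2887-1 limit, and leaving out 1 embryo gave from 0 to 97 genes. HSD11B1L was not called without any of control males 35, 36, 37, 51, 67, 70 or 72. Of the genes that did not pass, IGFBP2, a binding protein of insulin-like growth factors, averaged 49.2 ± 9.67 RPKM against 17.7 ± 5.78 RPKM. BEST2, an anion channel, averaged 1.36 ± 0.538 RPKM against 6.44 ± 1.74 RPKM.

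Of 24 lists in males, 10 were called by camera with the preset correlation. Cholesterol genes (median −0.57, adjusted p = 8.19e-05), nuclear oxidative phosphorylation genes (0.000272), trophectoderm genes (0.0022) and antioxidant genes (0.0333) were lower. Cell cycle (0.0155), epiblast (0.0343), heat shock (0.0343), growth factor receptor (0.0347) and chromatin genes (0.0347) were higher. Mitochondrially encoded genes were higher too (median 0.18, adjusted p = 0.0347), opposite to females. With an estimated correlation none was called, with adjusted p from 0.39 to 0.536, and all rest on 2 knockout males.

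The difference between the sexes in the genotype effect was tested by the interaction. Limma-trend called 0 of 6283 genes (smallest adjusted p = 0.999), with 94 at an unadjusted p under 0.05 where 314 would be there by chance, and voom called 0 with 151. That count was 727 with quality weights, 325 without the libraries in doubt, 245 above the bta-mir-2887-1 limit and 816 of 18442 genes without a filter. The named genes with a higher effect in males included LIN28A, an RNA-binding protein of pluripotent cells (1.45). Those with a lower effect included BNIP3, a mitophagy receptor (−2.50), and HSD11B1L (−1.91).

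Male and female blastocysts were compared as the other labelled factor. The level of X-linked genes relative to autosomal genes, as a difference of mean log2(RPKM + 1), was −0.38 ± 0.08 (SD) in 11 males and 0.13 ± 0.19 in 15 females (permutation p = 2e-05, the smallest possible, adjusted p = 0.0004). In morulae it was −0.28 ± 0.08 in 4 males and 0.17 ± 0.21 in 4 females (exact permutation p = 0.0286, adjusted p = 0.163). Limma-trend called 0 of 6283 genes between the sexes, with 685 at an unadjusted p under 0.05, 626 higher and 59 lower in males, and voom called 0 with 513 and 79. Of 198 X-linked genes 29 (14.6%) were lower in males at that p, and of 6085 others 30 were, though genes are not independent (Fisher's exact p = 9.42e-29). The median of all genes was 0.26. Without control 12 and knockout 57, the libraries in doubt and both labelled female, it was 0.0963, with 427 genes higher and 208 lower. Over all blastocysts it was 0.19 with median ratio scaling, where 374 genes were higher and 86 lower. It was −0.01 with quantile scaling, with 277 higher and 345 lower, which makes the distributions of all embryos equal by construction.

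Without the libraries in doubt, control 12 and knockout 57, a choice made after seeing the data, 27 genes passed between the sexes, 26 lower in males and 24 of these on chromosome X. MSN, a linker of membrane and actin, averaged 3.68 ± 0.840 RPKM in 11 males and 7.76 ± 1.55 RPKM in 13 females (log2 change −0.91 ± 0.13, adjusted p = 0.00245). Others on the X, named after their values were seen, were LAMP2 (−0.58), GLA (−1.01), VMA21 (−0.99), ATP6AP1 (−0.64) and TFE3 (−1.07). The 2 lower genes off the X were MYC (−1.54, chromosome 14) and HMOX1, or heme oxygenase (−1.72, chromosome 5), and the higher gene was SPPL2B (0.67). Over all embryos, none of the named genes passed. ASCL2, an imprinted regulator of trophoblast in mouse, averaged 7.39 ± 5.11 RPKM in males and 1.70 ± 2.14 RPKM in females, with 11 of 11 males above the female median. EXOSC2, an RNA exosome subunit (0.78), PRMT7 (0.69), bta-mir-12025 (2.86) and SPPL2B (0.87) were the others. HMGN5, RENBP, SAT1, PATZ1 and LGALS3BP were the named genes lower in males. No table holds XIST by symbol, and the gene labelled RPS4Y1 lies on chromosome 23, so no Y-linked gene could be read.

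Of 24 lists, 9 passed between the sexes with the preset correlation. The interferon response list, with 7 genes, was lower in males relative to other genes (adjusted p = 0.0023), held with an estimated correlation (adjusted p = 0.0413), and had a median of 0.05 where all genes had 0.26. The nuclear genes of oxidative phosphorylation were higher relative to other genes (median 0.88, adjusted p = 3.03e-09), and with an estimated correlation their adjusted p was 0.78. X-linked metabolic genes (adjusted p = 7.99e-09) and X-linked genes that can escape or mark inactivation (6.38e-05) were lower, and with an estimated correlation the adjusted p was 0.188 for both, or 0.00448 and 0.000903 without control 12. Mitochondrially encoded genes, ER stress, the p53 response, antioxidant genes and growth factor receptors were also lower relative to other genes, with adjusted p from 0.000203 to 0.0473, and from 0.432 to 0.78 with an estimated correlation. Without control 12 the adjusted p of mitochondrially encoded genes was 0.835, and the interferon response list had 0.0871 with an estimated correlation.

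**Figure D5:**
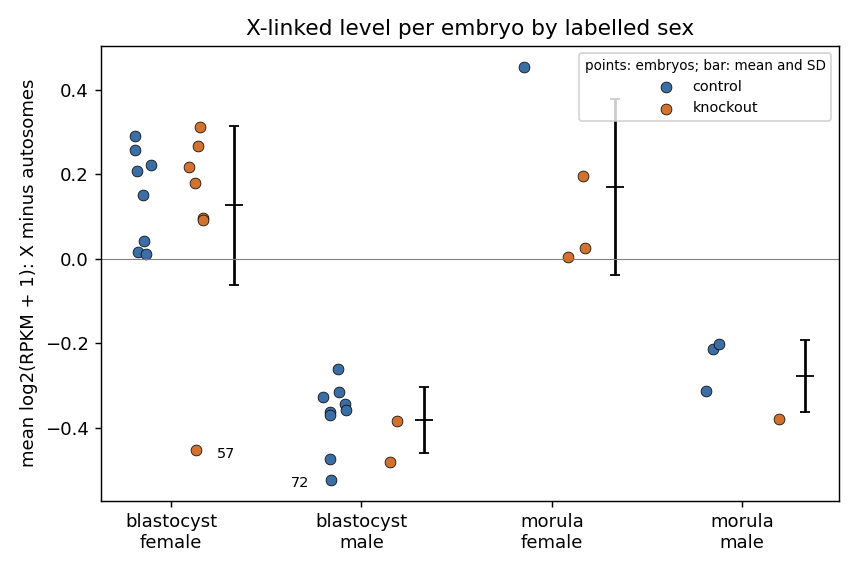
Mean log2(RPKM + 1) of X-linked genes minus that of autosomal genes per embryo (y axis), by labelled sex and stage (x axis), with bars for mean and SD. Labelled male blastocysts lay between −0.52 and −0.26, and knockout 57, labelled female, lay at −0.45.

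The genotype changes of the stages were set against each other over 4913 genes tested in both, in tables normalized separately. Across genes, which are not independent replicates, Spearman's rho was 0.0924 with a jackknife SE over embryos of 0.1822, and Pearson's r was 0.147. The changes had the same sign in 46.4% of these genes, and in 40.5% with a pseudocount of 0.1. All tested genes had medians of 0.08 in blastocysts and −0.34 in morulae, so this share cannot be set apart from these opposite shifts. Of the genes called in the deposited tables, 10 blastocyst and 27 morula genes lay among the 14494 genes in both tables, and 0 were shared (Fisher's exact p = 1). FDPS averaged 1.77 ± 1.25 RPKM in knockout and 3.67 ± 4.22 RPKM in control morulae (n = 4 each), and PAG2 22.2 ± 11.1 RPKM in 9 knockout and 27.6 ± 17.5 RPKM in 17 control blastocysts. Neither gene passed at those stages, and a difference of the genotype effect between stages was not tested.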

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

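The tests chosen only after the result was seen were those on single embryos and on a shared genotype difference in the deposited blastocyst calls, on depth, doubted libraries and sex in the morulae, and on a male embryo behind the label of knockout blastocyst 57. The runs of the list tests by sex without control blastocyst 12 were added after seeing the data too.

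Knockout blastocyst 57, the shallowest blastocyst library, stood apart in 3 measures and in its X-linked level. Its trophectoderm list mean was 3.228 where the other knockouts lay between 4.128 and 4.86. Its log2(RPKM + 1) was 2.904 for CSF2RA, with the other knockouts at 0, and 1.351 for CSF2RB, with the others up to 0.0686. With 2 reads behind each, and 3 reads as the limit of a count of 0 at 49.7 CPM in this library, these levels rest on single counts. Among 45 groups of 4 to 10 embryos tested for a sample far from the others, 6 were found and 2.25 were expected by chance. The flags for CSF2RA, CSF2RB and GCA rest on 1 or 2 reads where the other knockouts lay at or near 0. The expected number does not allow for such counts, so 6 against 2.25 shows no excess.

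The X-linked level of knockout 57, labelled female, was −0.4542, in the range of males. Low depth was tested by thinning 14 other female libraries to its 44879 reads, 100 times each, and the lowest value reached was −0.3168, which argues against depth alone. Thinned male libraries ran from −0.7599 to −0.1277 and include it, so a male embryo behind the label stays open as a candidate explanation. Control blastocyst 72, whose title and column name give different sexes, lay at −0.5241, among the males. A lost or silenced X chromosome in a female embryo was not tested, and the tables give no Y-linked gene to decide.

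Among the 15 genes called in the authors' blastocyst table, 1 embryo held over 50% of the CPM of the higher genotype in 14 of 15, and over 80% in 9 of 15, limits chosen after these shares were seen. A genotype difference shared by most embryos was met by 2 of 15 genes, those detected in over 50% of the embryos of the higher genotype and at least 2 times higher without the top embryo. Genes with 100 or more reads and over 90% of their CPM in 1 library occurred in 7 of 26 libraries, 1 of 9 knockouts and 6 of 17 controls. Control 12 alone held 70 of them and no other library over 1, and the read minimum favours the deeper control libraries, so this decides nothing on either genotype. Whether single embryos carry these transcripts or single libraries amplified them was not tested.

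Of the 10 genes lower in knockouts in the authors' morula table, 8 were lower than in every control in both knockout libraries not in doubt. A test on these same morulae picked the genes, so that count cannot decide on the doubted libraries. The trophectoderm list was fixed beforehand, and its means in those libraries, 3.531 and 3.762, lay below every control (4.339 or more). This argues against the doubted libraries as the only source of the lower trophectoderm list. It is not particular to that list, as the list mean was lower in knockouts for each of the 30 lists compared. At the depth of both knockout libraries not in doubt, 0 of 10 genes had reads within the Poisson range of the control mean, and 10 of 10 were lower within both sexes. Depth and sex stay open all the same, because that range covers counting alone, a single control was as shallow, each sex held an arm of 1 embryo, and a sex-blocked test on these morulae picked the genes. A less advanced stage might lower genes that rise later; the trophectoderm list rose from control morulae to control blastocysts by a median of 0.5177 where 95% of matched random lists stayed under 0.3965 (percentile 99.49), in tables normalized separately. The 10 genes had a median rise of 0.16 against a 95th percentile of 0.4811 (percentile 40.8), which decides nothing because the control morulae that picked them are the ones subtracted, so a stage lag stays open beside an effect of the knockout.

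The X-linked level of control morula 73, the female among the controls, was 0.455, where the 3 control males lay between −0.3125 and −0.2028. The trophectoderm list mean of knockout morula 21 was 1.7, where the other knockouts lay between 3.531 and 3.762. GCA was at 3.21 on the log2(CPM + 1) scale in knockout morula 5, from 1 read, and at 0 in the other knockouts.

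The genotype effect on 5 lists differed between male and female blastocysts, by camera on the interaction with the preset correlation. Relative to other genes the effect was higher in males for mitochondrially encoded genes (median 0.76, adjusted p = 2.08e-08), epiblast genes (0.40, adjusted p = 0.024), hypoblast genes (0.40, adjusted p = 0.0193) and interferon response genes (0.51, adjusted p = 0.0275). It was lower in males for nuclear oxidative phosphorylation genes (−0.77, adjusted p = 4.61e-05). With an estimated correlation the adjusted p were 0.247, 0.716, 0.716, 0.226 and 0.716, and the male effect rests on 2 knockouts. Without control blastocyst 12 the adjusted p were 0.00135 for mitochondrially encoded genes and 0.145 for interferon response genes with the preset correlation, and 0.254 for both with an estimated one.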

How the results depend on the processing

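The alternatives chosen only after the data were seen were voom, CPM, leaving out the libraries in doubt (alone or with quality weights), the bta-mir-2887-1 limit, embryo 72 as female, and list tests by sex without control 12 or the libraries in doubt. No paired analysis was possible because embryo numbers are unique across groups. Count tests were not run on RPKM, and of upper quartile and median ratio scaling the latter was run. The bta-mir-2887-1 limit left out control blastocysts only, control 12 among them. The cause of each change below was not tested.

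Genes called between knockout and control blastocysts stayed at 0 in every alternative except males only (2) and the authors' table (15), and at 0 on leaving out each embryo. Between knockout and control morulae the count of 0 became 44 with pseudocount 0.1, 31 with pseudocount 0.5 and 33 without sex in the model, all lower. It became 27 in the authors' table, 1 with voom (GCA) and 1 without the libraries in doubt (a gene without a symbol, higher), and stayed at 0 on leaving out each morula. In simulated morulae limma-trend made 37 calls on unchanged genes, 36 of them lower, where voom made 3, so lower calls can arise without a change. The simulation kept a pseudocount of 1 and sex in the model, a setting with 0 calls in the real morulae. The settings that gave 44, 31 and 33 calls were not simulated.

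For the interaction the count of 0 became 17 without a filter, 3 with quality weights (BNIP3 and GSC2 among them) and 1 above the bta-mir-2887-1 limit (GSC2). In females it became 5 with quality weights (FOXH1, TDGF1, ARHGAP5 and 2 without symbols), and leaving out 1 embryo gave 0 to 1 (without control 11). In males the count of 2 became 1 with pseudocount 0.1, 1 with pseudocount 0.5, 27 without a filter, 0 at a mean of 5 RPKM, 5 with quantile scaling, 7 without robust moderation, 0 with voom, 0 with CPM and 1 with embryo 72 as female, and above the bta-mir-2887-1 limit there were 3 others (GSC2 and 2 without symbols) and neither of the 2. Leaving out 1 male gave 0 (without control 36, 51, 67 or 70) to 97 (without knockout 75), with 79 without knockout 50, 4 without control 69 and 1 without control 35 or 72. In the runs without a knockout male, the lone knockout is assumed to vary like the controls. Between the sexes the count of 0 became 16 with quantile scaling, 127 with quality weights, 27 without the libraries in doubt and 127 with both, and leaving out 1 embryo gave 0 to 1 (MSN, without control 12).

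Of the lists, 2 were called in blastocysts. This became 0 with an estimated correlation, 0 with fry (which tests a list against no change, not against other genes), 3 without sex in the model (the p53 response higher, 0.0197) and 5 above the bta-mir-2887-1 limit, with cell junction (0.00368) and glycolysis genes (0.00754) lower and oxidative phosphorylation genes higher (2.13e-11). Leaving out 1 embryo gave 2 to 4 (without control 52, with oxidative phosphorylation higher and glycolysis lower, 0.0259 each). The cholesterol list had adjusted p = 0.542 with an estimated correlation and 0.891 with fry against no change, and from 9.35e-10 to 1.09e-05 on leaving out 1 embryo. The mitochondrially encoded genes had 0.542 and 0.891, 0.105 without the libraries in doubt, 0.153 above the bta-mir-2887-1 limit, and 1.43e-08 to 0.368 (without control 12) on leaving out 1 embryo. The trophectoderm list in blastocysts was higher with fry (0.996), lower and called without the libraries in doubt (0.0274) and above the bta-mir-2887-1 limit (0.00151), and ran from 0.00505 (without control 12) to 0.752. In morulae the 1 list called became 0 with an estimated correlation, 0 with fry, 2 without a filter and 4 without the libraries in doubt, where cell junction and glycolysis genes were also lower and oxidative phosphorylation genes higher, and leaving out 1 embryo gave 1 to 2 (without control 73). The trophectoderm list there had 0.929 with an estimated correlation and 0.417 with fry against no change, and 6.16e-05 to 0.0451 on leaving out 1 morula.

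On leaving out 1 embryo the CSF2RA change of 0.25 ran from −0.0453 (without knockout 57) to 0.3071, and that of CSF2RB from 0.0027 (without knockout 57) to 0.1576, and with pseudocount 0.1 they were 0.463 and 0.4139. Of the lists called by sex, mitochondrially encoded genes had 0.956 and growth factor receptors 0.0539 without the libraries in doubt, and interferon response genes had 0.152 there for the interaction. The correlation of genotype changes across genes between stages ran from 0.0869 to 0.1493 over its settings and from 0.0024 to 0.2029 on leaving out 1 embryo. Among single genes named in morulae, 195 results were on the same side of the threshold and 31 newly past it, and in blastocysts by genotype 314 and 0.

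What the tests recover was tried on simulated changes, where depth and group size differ together between the stages. Limma-trend recovered 40.3%, 80.6% and 90.9% of genes changed 2, 4 and 8 times in blastocysts, and 1.49%, 8.96% and 39.4% in morulae, where voom recovered 0%, 23.9% and 62.1%. The simulated spread likely understates that of real embryos.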

Other observations

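Over both sexes, lists that no comparison of the stages described were not called between genotypes by camera at either stage. Pro-apoptotic genes gave an adjusted p of 0.758 in blastocysts and 0.733 in morulae, anti-apoptotic genes 0.518 and 0.741, heat shock genes 0.758 and 0.733, hypoxia genes 0.821 and 0.733, and receptors of growth factors and cytokines 0.758 and 0.527. In blastocysts 8 of 9 anti-apoptotic genes were higher in knockouts, and in morulae 8 of 9 were lower, and no member passed adjusted over the list alone. The median change of all tested genes was 0.08 in blastocysts and −0.34 in morulae, so these counts cannot be set apart from the shift of all genes. In blastocysts that median was −0.07 without control 12. The ER stress list gave 0.758 in blastocysts. X-linked metabolic genes gave 0.758 in blastocysts, and X-linked genes that can escape or mark inactivation 0.93 and 0.527. Oocyte transcripts, with 3 of 28 listed genes past the filter in blastocysts, had a mean of 2.22 ± 0.79 (SD, n = 9) in knockouts and 2.33 ± 0.72 (n = 17) in controls (permutation within sex p = 0.923).

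Markers of other cell types were also read in morulae. Of 10 cumulus and granulosa markers listed in morulae, 2 passed the filter. These had a list mean of 0.826 ± 0.960 in knockouts and 2.59 ± 0.720 in controls (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.123). Oviduct epithelium markers gave an exact p of 0.686, leukocyte markers 0.457 and erythrocyte markers 0.743. Male morulae had a median of 10710 detected genes and female morulae of 6408 (exact permutation p = 0.0286, adjusted p = 0.163), and 3 of 4 males were controls.

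Other splits of the same embryos were fitted to see how often they gave as much, in tests chosen beforehand. Each count and each total of splits below includes the real split. For knockout against control blastocysts 50 of 100 splits gave at least the 173 genes at an unadjusted p under 0.05, and the highest other gave 1293. For morulae 7 of 34 splits gave at least the 345 genes, with 492 as the highest other; 1 of the 35 splits followed sex and could not be fitted. For female blastocysts 87 of 100 gave at least 108, with 546 as the highest other, and for the sexes 5 of 100 gave at least 685, with 1020 as the highest other. For the smallest list p, as −log10, 28 of 100 blastocyst splits reached 8.393, with 22.09 as the highest other, and 19 of 34 morula splits reached 4.525, with 11.16 as the highest other. Chance is not excluded for any of these 6 results. The blastocyst splits that gave several times the real count, 1293 against 173 and 546 against 108 in females, point to a structure of the samples, which was not tested.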
